A study of Homo sapiens with 6 samples.

How the data were processed

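MicroRNA (miRNA) levels were measured on 6 one-colour Agilent arrays. MM.1S and KMS-11, established human multiple myeloma cell lines, were each cultured for 48 h with DMSO, with 10 nM panobinostat or with 1 µM vorinostat, with 1 array per line and drug. Per the labels, the cells grew in RPMI1640 with 10% fetal serum, and total RNA was extracted with Trizol and labelled with Cy3. The drug defines the group, and the cell lines are the only replicates of a drug (n = 2 arrays per drug). Nothing says that further cultures stand behind an array, so p-values measure only the spread between these arrays after the mean difference between the lines is taken out.

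Per the file headers, the spot values are intensity values from Agilent Feature Extraction 11.5.1.1, background-subtracted by that software, on a linear scale and not scaled between arrays. The deposited value table is on a log2 scale. For detected miRNAs it equals log2 of the software's total signal per miRNA plus a negative offset that is nearly constant within an array. The median offset per array runs from −4.40 to −2.51, and at most 4 detected miRNAs per array lie more than 0.01 from it. On each array 1620 to 1718 of the 2006 miRNAs share the lowest value, which is all of the undetected miRNAs except 1 on the MM.1S vorinostat array and 5 on the KMS-11 DMSO array. The reason for that constant is not stated, and the values are not centred per miRNA. The deposited spot table of the MM.1S panobinostat array is damaged in its middle, where 1001 lines of another kind of file, whose values are in other units, replace 131 spots. The 62213 whole spots of the 62344 on the array were used.

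For each probe, the background-subtracted signal was averaged over its spots, leaving out spots that the software marked as outliers (2.70% to 3.09% of miRNA spots). The probes of a miRNA were summed. Each array was divided by its 75th percentile over the 242 miRNAs detected on all 6 arrays. Values under a floor of 0.0291 (−5.10 on the log2 scale) were set to that floor, and log2 was taken. The 362 of 2006 miRNAs that the software called detected on at least 2 of the 6 arrays were tested. A change against an array on which a miRNA was undetected rests on the floor or on signal under detection there, as for miR-188-5p and miR-4534 with DMSO in KMS-11, miR-192-5p and miR-194-5p with DMSO in MM.1S, and miR-212-3p, miR-431-3p, miR-487b and miR-3907 with panobinostat in MM.1S. Values are relative to the upper quartile of the array's own common miRNAs. With spike-in scaling, the median change of the tested miRNAs under both inhibitors moved from −0.10 to 0.38, and without scaling to 0.33.

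limma 3.58.1 in R 4.3.3 fitted cell line and drug to all 6 arrays, with 2 residual degrees of freedom per miRNA and a shared prior of 52.2 degrees of freedom. Contrasts were each inhibitor against DMSO, the mean of both inhibitors against DMSO, panobinostat against vorinostat, and KMS-11 against MM.1S. Cell line is the block that pairs each treated array with the DMSO array of its line. Within a line the deviations from the drug means correlated across miRNAs at 0.83 to 0.93, and miRNAs are not independent replicates. A further limma fit tested the interaction of line with inhibitor, taking the inhibitors as a pair of treated arrays per line. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 362 miRNAs, and a call is an adjusted p under 0.05. The SE given after ± and the 95% intervals are those of the moderated fit. With 2 residual against 52.2 prior degrees of freedom, they rest mostly on variance pooled over miRNAs. They do not measure the spread of a single miRNA between the lines. The number of arrays limits the precision: the median interval reached 0.72 either side of the estimate for 1 inhibitor and 0.63 for both. In data simulated with this design (20 simulations of 362 miRNAs), 99.3% of 4-fold and 39.5% of 2-fold panobinostat changes were recovered, 98.8% and 41.8% for vorinostat, and 99.8% and 61.7% for both inhibitors. False calls made up 5.34%, 4.63% and 4.81% of the simulated calls. The simulation drew independent noise from the fitted prior and planted the same change in both lines. These rates therefore hold only under the assumptions of the fit and do not measure the error of the real calls.

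A change common to all 4 treated arrays was counted at 2-fold or more against the line's own DMSO array, with a one-sided Fisher's exact test of the overlap between the lines. Within a line the inhibitors share 1 DMSO array, so their chance correlation was simulated 100 times. miRNA lists were tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, where at least 3 members were tested (15 of the lists). The 26 lists covered miR-7, oncogenic clusters, differentiation and p53-linked families, NF-kB-linked, lymphoid, neuronal and methylation-silenced miRNAs, miR-210, imprinted and testis clusters, and markers of muscle, liver, erythroid, myeloid and stromal cells. The miR-7 list was chosen by the study on these samples and is not independent evidence.

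The lists, the tests, the alternatives and the rule for named miRNAs were fixed before the data were examined. The rule took, for each drug contrast and for both inhibitors, the 10 highest and 10 lowest miRNAs by the smaller of the 2 lines' changes, among those moving the same way in both lines, with called ones first. It took 5 each way for panobinostat against vorinostat and for the interaction, 10 each way by fitted change for the lines, and miR-7-5p. It added 2 to 4 members of each list with the smallest p, and the members of the common change. Other miRNAs named below were chosen after their values were seen.

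Alternatives were 5 other scalings (the 75th percentile over all miRNAs, the median, quantile, none and spike-ins), normexp background correction with an offset of 50, the software's total signal, the brightest probe, the deposited value table, floors 4 times lower and higher, and filters at all 6 arrays, at least 1 array and none. With 288 to 386 of 2006 miRNAs detected per array, the 75th percentile over all miRNAs lies among undetected ones. That scaling therefore divides by signal under detection. Others left out cell line from the fit, used only the arrays of 1 inhibitor and DMSO, changed the variance prior, or left out each array in turn. Normexp used the median spot signal because the files hold no mean. Slide and scan could not be blocks, since the files show 1 slide and 1 scan. Tables were read with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9. A RefSeq gene table (GRCh38.p14) gave precursor gene names for 287 of the tested miRNAs. The array grid uses build hg19, which differs from that of the table, so no coordinates are printed.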

Results

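To follow miRNAs in myeloma cells under histone deacetylase (HDAC) inhibition, total RNA of MM.1S and KMS-11 was profiled after 48 h with DMSO, 10 nM panobinostat or 1 µM vorinostat. Each line and drug had 1 array, giving 2 arrays per drug and 3 per line. In MM.1S, 306 of the 2006 miRNAs on the array were detected with DMSO, 386 with panobinostat and 337 with vorinostat. In KMS-11 the counts were 296, 290 and 288. The 10 brightest miRNAs held 87.8%, 72.6% and 82.1% of the total signal in MM.1S and 88.4%, 89.1% and 88.8% in KMS-11. All 6 arrays lay on 1 slide with 0 saturated spots, MM.1S in one row and KMS-11 in the other. In both rows DMSO lay in column 1, panobinostat in column 2 and vorinostat in column 3. An effect of the drug therefore cannot be told apart from one of slide column, nor the line from slide row. The median coefficient of variation between spots of a probe was 5.72% to 7.26%. Before scaling, the 75th percentile of the common miRNAs stood 1.21 log2 units above DMSO in panobinostat-treated MM.1S and 0.53 above it with vorinostat. In KMS-11 the shifts were 0.12 and 0.06, and the spike-in controls moved by −0.16 to 0.04 over the 4 treated arrays.

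Panobinostat, a hydroxamate HDAC inhibitor, was set against DMSO to find the miRNAs that respond to it. Of 362 miRNAs tested, 6 fell and 2 rose. The lowest was miR-7-5p, at −1.72 ± 0.36 on the log2 scale (moderated SE, n = 2 lines, 95% interval −2.44 to −1.01, limma adjusted p = 0.00437), a 3.30-fold decrease. It was followed by miR-210, a miRNA induced by hypoxia, at −1.63 ± 0.37 (adjusted p = 0.0111). miR-1260b (−1.52, adjusted p = 0.0233), miR-1260a (−1.42), miR-5100 (−1.35) and miR-17-3p, an arm from the MYC-driven miR-17/miR-92a cluster (−1.31), also fell, each of the last 3 at an adjusted p of 0.0465. miR-129-2-3p, whose gene is silenced by methylation in blood cancers, rose by at least 2.75-fold, since it was detected on neither DMSO array and was set to the floor there (fitted change 1.46 ± 0.37, adjusted p = 0.0233). miR-630 rose by 1.26 ± 0.36 (adjusted p = 0.0465). All 8 moved the same way in both lines, but not by the same amount: miR-7-5p changed by −1.92 in MM.1S and −1.52 in KMS-11, miR-17-3p by −2.04 and −0.57, and miR-5100 by −2.50 and −0.20. Below the threshold, miR-18a-5p (−1.24, adjusted p = 0.0509), miR-18b-5p (−1.19), miR-7-1-3p (−1.07), miR-431-3p (−1.01) and miR-212-3p (−0.86) had negative values in both lines. Positive values were seen for miR-5703 (1.20, adjusted p = 0.0633), miR-188-5p (1.02), miR-5787 (1.02), miR-1246 (0.78), miR-2392 (0.65), miR-3135b (0.58), miR-181a-5p (0.51) and miR-194-5p (0.41). In all, 79 miRNAs had an unadjusted p under 0.05, where 18.1 would by chance. The 8 calls became 0 with cell line left out of the fit (0 at an unadjusted p under 0.05, limma), 2 (miR-7-5p and miR-129-2-3p) without the MM.1S DMSO or the MM.1S panobinostat array, 0 without either vorinostat array (36 at an unadjusted p under 0.05), and 96 and 152 without the KMS-11 DMSO and panobinostat arrays. Median, quantile, spike-in or no scaling also gave 0 (23 to 43 at an unadjusted p under 0.05), and normexp background correction turned miR-129-2-3p to −0.20.

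For vorinostat, also a hydroxamate, the same question gave 1 call among the 362 miRNAs. miR-210 fell by 1.89 ± 0.37 on the log2 scale (moderated SE, n = 2 lines, 95% interval −2.64 to −1.14, limma adjusted p = 0.00184), a 3.72-fold decrease, with −2.53 in MM.1S and −1.26 in KMS-11. miR-7-5p was at −1.28 ± 0.36 (interval −1.99 to −0.56), 2.42-fold lower, which did not pass the correction (adjusted p = 0.138). Other negative values in both lines were miR-431-3p at −1.14 (adjusted p = 0.186), miR-18a-5p at −1.07, miR-3907 at −1.03, miR-18b-5p at −1.0, miR-17-3p at −0.99, miR-17-5p at −0.89 and let-7i-5p at −0.79. Ranked by the smaller of the lines' changes, the 10 highest miRNAs were miR-5703 at 1.22 and miR-630 at 1.15 (adjusted p = 0.186 for both), miR-4739 at 0.92, miR-1229-5p at 0.89, miR-6068 and miR-4534 at 0.83, miR-22-3p at 0.81, miR-1234-5p at 0.80, miR-5787 at 0.79 and miR-194-5p at 0.59. miR-129-2-3p was at least 1.80-fold higher than DMSO but was not called. An unadjusted p under 0.05 was found for 40 miRNAs. No miRNA was called with cell line left out of the fit (0 at an unadjusted p under 0.05, limma), nor without the MM.1S DMSO array or either vorinostat array (10, 5 and 1 at an unadjusted p under 0.05), whereas 25, 39 and 25 were called without the MM.1S panobinostat, KMS-11 DMSO and KMS-11 panobinostat arrays. Scaling by the 75th percentile over all miRNAs gave 2 higher (miR-630 and miR-5703) and 1 lower (miR-210), in place of 0 and 1, and median, quantile, spike-in or no scaling gave 0 (9 to 23 at an unadjusted p under 0.05).

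The mean of both inhibitors was set against DMSO because the study looked for miRNAs that change under both drugs, although 1 drug alone can move that mean. Here 7 miRNAs fell and 3 rose. miR-210 fell by 1.76 ± 0.32 (moderated SE, n = 2 lines, 95% interval −2.41 to −1.11, limma adjusted p = 0.000488), 3.39-fold. miR-7-5p was at −1.50 ± 0.31 (interval −2.12 to −0.88, limma adjusted p = 0.00201), a 2.83-fold decrease. miR-18a-5p and miR-17-3p, both from the miR-17/miR-92a cluster, were at −1.15 (adjusted p = 0.0377 for each), and miR-18b-5p, from the paralogous miR-106a-363 cluster, was at −1.10 (adjusted p = 0.041). miR-1260b (−1.15, adjusted p = 0.0443) and miR-431-3p (−1.08, adjusted p = 0.041) fell too, although miR-431-3p was detected on no MM.1S array and its value there rests on signal between the floor and detection. miR-630 and miR-5703 rose by 1.21 (adjusted p = 0.0309 for each) and miR-129-2-3p, undetected with DMSO, by at least 1.15 (adjusted p = 0.0377). All 10 had the same sign in both lines, and the changes in MM.1S were the larger for most, as with miR-210 (−2.48 in MM.1S and −1.04 in KMS-11). The fit takes the inhibitor effect as equal in both lines and counts such line differences as independent noise of single arrays. The treated arrays of a line also share its DMSO array, so these intervals and adjusted p-values may be too small. Not called were miR-7-1-3p (−0.93, adjusted p = 0.0843), miR-212-3p (−0.85), let-7i-5p (−0.81), miR-1229-5p (0.94), miR-5787 (0.91), miR-192-5p (0.90), miR-188-5p (0.82) and miR-1246 (0.71). An unadjusted p under 0.05 was found for 79 miRNAs. The count was 0 with cell line left out of the fit (0 at an unadjusted p under 0.05, limma) and 0 without the MM.1S vorinostat array (20 at an unadjusted p under 0.05), 1 without the MM.1S DMSO array (miR-129-2-3p) or the KMS-11 vorinostat array (miR-210), and 89 and 153 without the KMS-11 DMSO and panobinostat arrays. Scaling by the 75th percentile over all miRNAs gave 6 higher and 2 lower, and median, quantile, spike-in or no scaling gave 0 (21 to 40 at an unadjusted p under 0.05), while normexp turned miR-129-2-3p to −0.13.

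**Figure D1:**
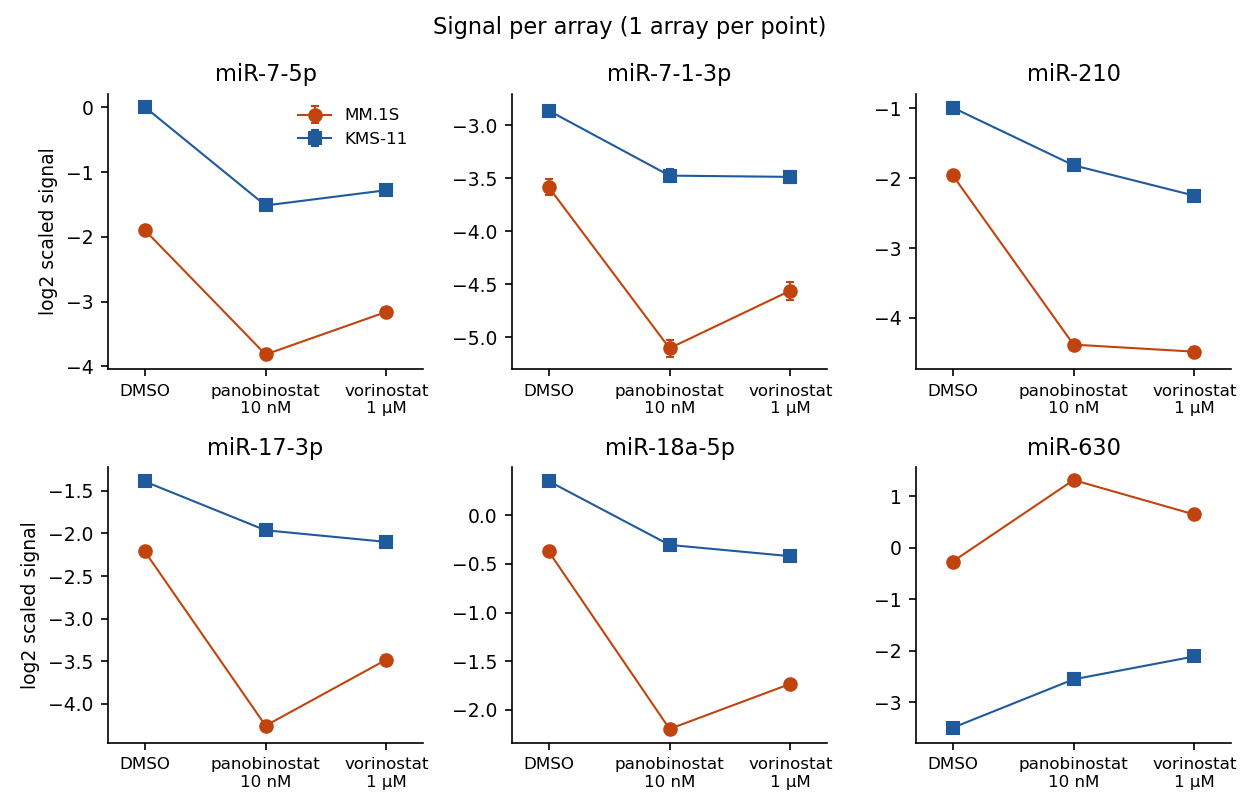
Log2 scaled signal of 6 miRNAs on each array (y axis), by line and drug (x axis), 1 array per point, with bars for the standard error between spots. miR-7-5p went from −1.89 with DMSO to −3.82 and −3.16 in MM.1S, and from 0.01 to −1.52 and −1.28 in KMS-11.

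**Figure D2:**
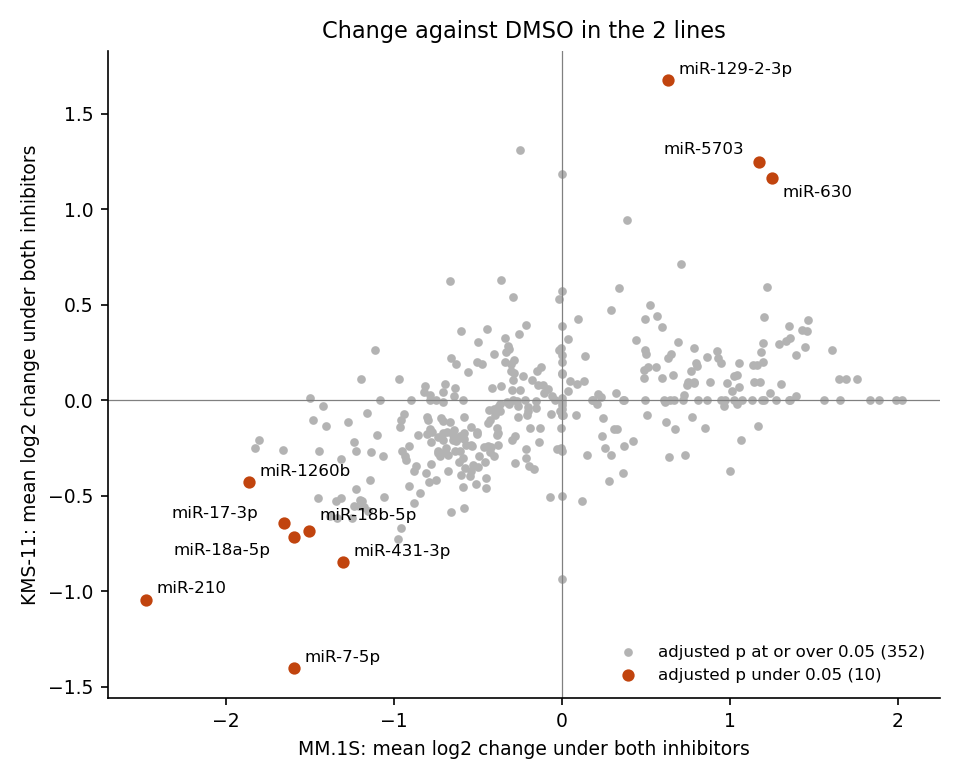
Log2 change from DMSO, mean of both inhibitors, in MM.1S (x axis) and KMS-11 (y axis), 1 point per tested miRNA, with the 10 called miRNAs marked apart from the 352 others. miR-7-5p lies farthest down in KMS-11 among the called miRNAs, and the spread along the MM.1S axis is the wider.

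The lists were then used to ask whether groups of miRNAs moved together. All 9 tested arms of the miR-17/miR-92a cluster, a MYC-driven oncogenic cluster, were below DMSO, with a median of −0.87 under both inhibitors (−0.99 for panobinostat, −0.76 for vorinostat). Of these, 2 fell over all 362 miRNAs, miR-17-3p and miR-18a-5p, and 7 were called when adjusted over the list alone, as with miR-17-5p at −0.98 and miR-92a-3p at −0.85. camera placed the list below the other miRNAs for panobinostat (adjusted p = 0.000506), vorinostat (adjusted p = 0.00016) and both (adjusted p = 0.000252), but not with an estimated correlation (adjusted p = 0.86, adjusted p = 0.951 and adjusted p = 0.878). The 5 tested members of the paralogous miR-106b-25 and miR-106a-363 clusters had a median of −0.62, with 1 that fell (miR-18b-5p) and 2 called when adjusted over the list alone (also miR-20b-5p at −0.88). Their list was called as lower at the preset correlation for panobinostat (adjusted p = 0.0386), vorinostat (adjusted p = 0.0319) and both inhibitors (adjusted p = 0.0319), and with an estimated correlation again not (adjusted p = 0.86, adjusted p = 0.951 and adjusted p = 0.878). In MM.1S, 1 miR-20b-5p probe changed by −1.44 with panobinostat and −0.96 with vorinostat, and 1 miR-20a-5p probe by −1.39 and −0.89. In KMS-11 the same probes changed by −0.52 and −0.56, and by −0.53 and −0.60. Whether the probes tell such paralogs apart was not tested, so this list is not separate evidence for other loci. All 9 arms of miR-17/miR-92a stayed negative under each of the 5 other scalings (medians −0.79 to −0.34), while 1 of the 5 paralogs turned positive without scaling or with spike-ins. The paralog list was no longer called without either DMSO array or the KMS-11 panobinostat array, and the miR-17/miR-92a list was called without each array.

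The other lists tested were not called by camera in the main fit. For both inhibitors, the let-7 and miR-98 list was called in 7 of 23 settings at the preset correlation, and the miR-181 list in 2 of 22. All 8 tested let-7 and miR-98 members, a differentiation-associated family, had negative values (median −0.42, adjusted p = 0.132), as had all 7 of the miR-15/16 family (median −0.43, adjusted p = 0.176), with 0 called even when adjusted over the list alone. Both medians turned positive without scaling (0.06 and 0.03) and with spike-ins (0.11 and 0.08). The 5 p53-responsive miRNAs had a median of 0.10 (adjusted p = 0.382), with miR-192-5p at 0.90 called only when adjusted over the list alone and miR-34a-5p at −0.02. Among NF-kB-linked miRNAs 6 of 8 were positive (median 0.26, adjusted p = 0.453), as were 4 of 5 in the miR-181 family (median 0.07, adjusted p = 0.453). Of 8 miRNAs silenced by CpG methylation 1 rose, miR-129-2-3p, with a list median of 0.08 (adjusted p = 0.573). In the imprinted DLK1-DIO3 cluster 1 of 5 tested miRNAs fell, miR-431-3p, and 2 were called when adjusted over the list alone, the other being miR-487b at −0.78 (list median −0.39, adjusted p = 0.453). The neuronal list had a median of −0.15 (adjusted p = 0.679), with miR-212-3p called only when adjusted over the list alone. Medians were −0.29 for 11 lymphoid miRNAs, −0.14 for the miR-23/24/27 clusters and −0.13 for the miR-29 family (adjusted p = 0.679 for each), and 0.17 for 3 members of the X chromosome miR-506 cluster (adjusted p = 0.637). The miR-30 family had a median of −0.09 and a mean of −0.04, while camera gave it the opposite sign (adjusted p = 0.933). For vorinostat, camera likewise opposed the negative medians of the miR-29 family (−0.03) and the X chromosome cluster (−0.07). Without scaling or with spike-ins, the negative medians of the DLK1-DIO3, neuronal, lymphoid, miR-23/24/27, miR-29 and miR-30 lists turned positive.

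Lists with fewer than 3 tested members had no camera test. In the miR-7 list, chosen by the study on these samples and so not independent evidence, miR-7-5p fell, and both members were called when adjusted over the list alone (median −1.22). miR-210 was the only member of the hypoxia list. miR-221-3p and miR-222-3p, which repress the cell cycle inhibitor CDKN1B, were at −0.43 and −0.54, miR-141-3p and miR-200c-3p of the epithelial miR-200 family at −0.38 and −0.14, and miR-371a-5p and miR-371b-5p of the stem cell miR-371 cluster at −0.17 and 0.66. Markers of other cell types were nearly absent: 0 of 8 muscle, 0 of 5 erythroid, 0 of 4 myeloid and 0 of 4 liver miRNAs were detected on any array. Of 11 stromal and endothelial miRNAs 1 was detected, miR-126-3p, at 0.19 under both inhibitors, and of 44 in the chromosome 19 cluster 1 was detected, miR-520b, on too few arrays to be tested.

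**Figure D3:**
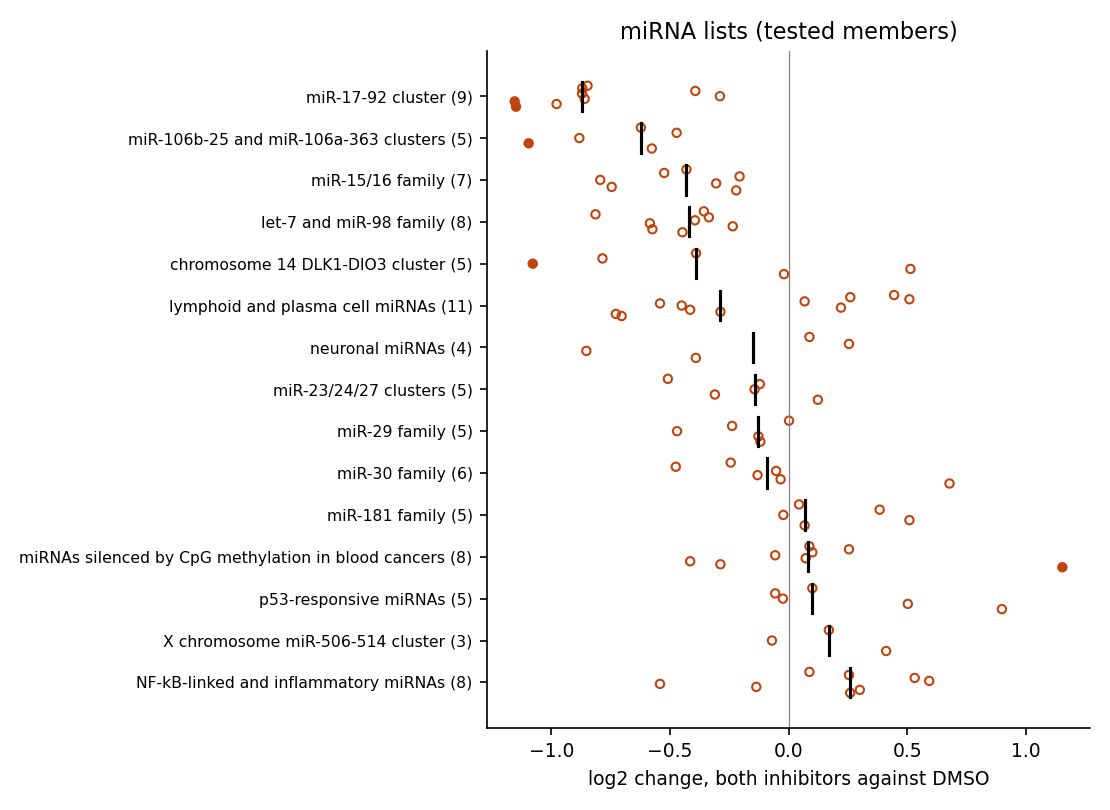
Log2 change from DMSO under both inhibitors (x axis) for the tested members of the 15 lists tested by camera (y axis), 1 point per miRNA, filled at an adjusted p under 0.05, with a bar at each list's median. All 9 miR-17/miR-92a arms lie below 0, with 2 filled.

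Because the series reports miR-7-5p as lowered in common, miRNAs at least 2-fold lower on all 4 treated arrays were counted. miR-7-5p was the only one, with changes of −1.92 and −1.26 in MM.1S (panobinostat, then vorinostat) and −1.52 and −1.29 in KMS-11. The spots of miR-7-5p on an array varied with a standard error of 0.95% to 4.17%. miR-7-1-3p, from the opposite arm of 1 of the miR-7 precursors, changed by −1.52, −0.98, −0.61 and −0.63. In MM.1S 25 miRNAs were 2-fold lower under both drugs and in KMS-11 only miR-7-5p was, so an overlap of 1 compares with 0.0691 expected, and the one-sided Fisher's exact test cannot give a smaller p than 0.0691 for these counts. No miRNA was 2-fold higher on all 4 arrays (20 in MM.1S, 3 in KMS-11, Fisher's exact p = 1). At 1.5-fold, 7 were lower in all 4 against 1.75 expected (miR-7-5p, miR-7-1-3p, miR-210, miR-18a-5p, miR-18b-5p, miR-212-3p and miR-431-3p; Fisher's exact p = 0.000125), and 2 were higher (miR-630 and miR-5703; p = 0.343, same exact test). The test takes miRNAs as independent, but the 7 include miR-7-5p with miR-7-1-3p and the paralogs miR-18a-5p and miR-18b-5p, and miR-212-3p and miR-431-3p were undetected on the treated MM.1S arrays. The count at 2-fold became 0 with the 75th percentile over all miRNAs, spike-in or no scaling or normexp, where miR-7-5p stayed negative on the mean of both drugs at −1.25, −0.97, −1.02 and −0.85, and it was 2 without the KMS-11 panobinostat array. Without scaling or with spike-ins, 2 miRNAs were at least 2-fold higher on all 4 arrays, miR-630 and miR-5703.

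The inhibitors were also compared with each other, at 10 nM for panobinostat and 1 µM for vorinostat. These are 1 dose of each and the doses differ, so a difference in response cannot be assigned to the compounds. The largest fitted differences towards panobinostat were miR-424-3p (0.72, 95% interval −0.04 to 1.48), miR-6073 (0.72), miR-129-2-3p (0.61), miR-6129 (0.51) and miR-513c-5p (0.48). Of these, all but miR-129-2-3p were detected on no KMS-11 array and on neither DMSO array, so their values rest on the MM.1S treated arrays and on signal under detection elsewhere. In the other direction stood miR-1260a (−0.75, interval −1.54 to 0.03), miR-1260b (−0.74), miR-5100 (−0.69), miR-3676-5p (−0.66) and miR-4443 (−0.64). For miR-7-5p the difference was −0.45 (interval −1.16 to 0.27) and for miR-210 it was 0.26 (interval −0.49 to 1.01). None of the 362 passed the test (limma, lowest adjusted p = 1, 0 at an unadjusted p under 0.05), and the median interval reached 0.72 either side, so differences of that size remain possible for most miRNAs. By chance 18.1 would have an unadjusted p under 0.05. The fit counts differences in response between the lines as noise, so these p-values may be too large. The lack of calls does not show that the inhibitors act alike. Without the KMS-11 panobinostat array 15 were called.

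Agreement of the changes was described across the 362 miRNAs, which are not independent replicates. Panobinostat and vorinostat changes correlated at a Pearson r of 0.92 in MM.1S (Spearman rho 0.92) and 0.75 in KMS-11 (rho 0.72), but the drugs share the DMSO array of a line, and noise alone gave 0.50 in each line over 100 simulations. The covariance was 0.628 in MM.1S against 0.132 in the simulated noise, and 0.0947 in KMS-11 against 0.135. That noise had the same spread in both lines, taken from the fit, whose residuals hold the differences in response between the lines. It is therefore not the noise of either line, and the covariances cannot be judged against it. The simulated r of 0.50 follows from a shared array with equal spread. Between the lines, which share no array, the mean changes under both drugs correlated at 0.50 (rho 0.57) against −0.01 from noise, with 74.1% of miRNAs of the same sign. The simulated noise held no effect of slide column, which the lines share for each drug. For panobinostat alone r between the lines was 0.33 (rho 0.41) and for vorinostat 0.54 (rho 0.58). The changes were wider in MM.1S, with a standard deviation of 1.04 under panobinostat and 0.65 under vorinostat, than in KMS-11 with 0.34 and 0.37. At least 2-fold changes numbered 72 higher and 61 lower in panobinostat-treated MM.1S, 20 and 25 with vorinostat, 3 and 1 in panobinostat-treated KMS-11, and 6 and 3 with vorinostat. The between-line r fell to 0.20 in the deposited value table.

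KMS-11 was compared with MM.1S over the 3 arrays of each, with drug as a term. The values are means over DMSO and both inhibitors. They therefore hold any difference in response between the lines besides the difference between the untreated lines. The lines differed in 206 of 362 miRNAs, 106 higher in KMS-11 and 100 higher in MM.1S. Highest in KMS-11 were the lymphoid miR-181a-5p (4.76 ± 0.29, moderated SE, n = 3 arrays per line, limma adjusted p = 2.27e-20), the oncogenic miR-21-5p (4.72 ± 0.31, adjusted p = 2.36e-19) and miR-181b-5p (4.70 ± 0.29, adjusted p = 2.75e-20), followed by miR-1246 (3.19), miR-125b-5p (2.95), miR-342-3p (2.81), miR-99a-5p (2.78) and miR-1260b (2.40). miR-21-3p and miR-181a-3p were detected on no MM.1S array and were at least 10.8-fold and 9.76-fold higher in KMS-11. Highest in MM.1S was miR-150-5p, a miRNA of mature lymphocytes, which was detected on no KMS-11 array and was at least 33.1-fold higher (fitted −5.05 ± 0.30, adjusted p = 7.88e-21). miR-30a-5p, at least 5.62-fold higher in MM.1S, was likewise undetected in KMS-11, and miR-5787 (−3.30), miR-630 (−3.29), miR-5703 (−3.18), miR-4516 (−2.74), miR-4739 (−2.66), miR-3960 (−2.54), miR-6090 (−2.53) and miR-188-5p (−2.45) were higher in MM.1S as well. miR-7-5p (2.03) and miR-210 (1.92) were higher in KMS-11.

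By list, all 5 miR-181 members were higher in KMS-11 (median 3.29, camera adjusted p = 0.000494; adjusted p = 0.755 with an estimated correlation), as were all 9 miR-17/miR-92a arms (median 1.40, adjusted p = 0.00471; adjusted p = 0.879 with an estimated correlation), and both kept these signs under every scaling. No other list was called by camera. All 5 miR-106b-25 and miR-106a-363 members (median 0.77), miR-221-3p and miR-222-3p (2.14 and 1.20) and both miR-7 members (median 1.58) were higher in KMS-11. Of the p53-responsive miRNAs, miR-34c-5p (at least 4.07-fold, undetected in MM.1S), miR-34b-5p (1.88) and miR-192-5p (0.82) were higher in KMS-11 and miR-34a-5p (−1.84) in MM.1S. Of 8 NF-kB-linked miRNAs 3 were higher in KMS-11, both miR-21 arms and miR-125b-5p, and 4 in MM.1S, among them miR-146a-5p (−2.0) and miR-155-5p (at least 1.79-fold, undetected in KMS-11). This list had a median of −0.30, a mean of 0.84 and a positive camera direction (adjusted p = 0.421). Among 11 lymphoid miRNAs 7 were higher in KMS-11 and 3 in MM.1S. In the let-7 family let-7c (2.26), let-7b-5p (1.70) and miR-98-5p (1.51) were higher and let-7g-5p (−0.68) lower, and 5 of 7 in the miR-15/16 family were higher, with miR-497-5p at 1.67. Of the methylation-silenced miRNAs 5 were higher in KMS-11 and 1 in MM.1S (miR-9-3p, −0.74). The neuronal list had 1 each way, miR-212-3p (1.11) and miR-9-3p, and the DLK1-DIO3 cluster also 1 each way, miR-431-3p (at least 3.66-fold higher in KMS-11, undetected in MM.1S) and miR-134 (at least 2.44-fold higher in MM.1S, undetected in KMS-11), with a median of −0.05, a mean of 0.15 and a positive camera direction (adjusted p = 0.834). miR-134 was detected on neither DMSO array, and in MM.1S only with the inhibitors. Its value is therefore not a difference between the untreated lines. All 3 miR-506 cluster members were lower in KMS-11 (median −0.70), as were miR-24-3p (−1.18) and miR-23a-3p (−0.80) of the miR-23/24/27 clusters and miR-371b-5p (−1.43). miR-29b-1-5p (0.98) of the miR-29 family and miR-126-3p of the stromal list (at least 2.80-fold, undetected in MM.1S) were higher, miR-30a-5p was the 1 call in the miR-30 family, and 0 of 2 were called in the miR-200 family.

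The balance between the lines depended on the processing: without scaling 41 miRNAs were higher in KMS-11 and 77 in MM.1S, and with spike-ins 52 and 93, in place of 106 and 100, and the median of all tested miRNAs moved from 0.03 to −0.59 and −0.55. Normexp gave 104 higher in KMS-11 and 33 in MM.1S, a filter at 1 array or more 42 and 14, and the 75th percentile over all miRNAs 79 and 98. The count of 206 was 118 without scaling, 124 without either vorinostat array, and 0 without a filter on dim miRNAs or with a floor 4 times higher (126 and 86 at an unadjusted p under 0.05, limma).

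**Figure D4:**
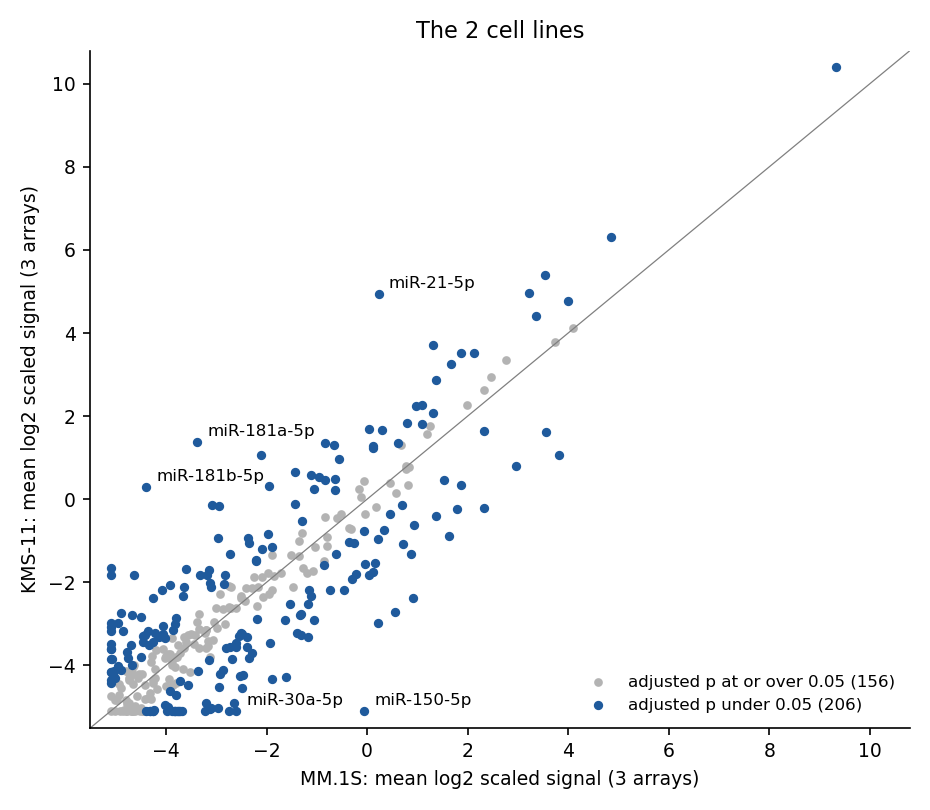
Mean log2 scaled signal of the 3 arrays of MM.1S (x axis) and of KMS-11 (y axis), 1 point per tested miRNA, with the 206 called miRNAs marked apart from the 156 others and the line of equality drawn. miR-181a-5p, miR-181b-5p and miR-21-5p lie above the line and miR-150-5p and miR-30a-5p below it.

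Whether the inhibitors acted differently in the lines was tested with the interaction of line and inhibitor. The largest fitted differences towards KMS-11 were miR-5100 (1.60), miR-1260a (1.57), miR-21-5p (1.56 ± 0.32, 95% interval 0.67 to 2.45), miR-15b-3p (1.52) and miR-1260b (1.43). Those towards MM.1S were miR-345-5p (−2.02), miR-718 (−1.99), miR-1471 (−1.89), miR-4689 (−1.83) and miR-4634 (−1.66). miR-345-5p, miR-718, miR-1471, miR-4689 and miR-4634 were detected on no KMS-11 array. For miR-7-5p the difference was 0.19 and for miR-210 it was 1.43. None of the 362 passed the test (limma, lowest adjusted p = 0.349, 45 at an unadjusted p under 0.05), with a median interval reaching 0.92 either side, so with these settings the effects were not shown to differ between the lines. Normexp called 5, among them miR-21-5p (adjusted p = 0.0276), the deposited value table called 22, and fitting without the MM.1S vorinostat array called 90.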

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

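In this part, the tests of array brightness, of name classes, of scaling, of single probes and of the opposite arm of miR-7-1 were chosen only after the results were seen, while those of the signal trend and of random lists were written down before.

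The number of detected miRNAs moved in opposite directions in the lines. Against the DMSO array of its line it changed by 80 with panobinostat and 31 with vorinostat in MM.1S, and by −6 and −8 in KMS-11, and this difference was not tested. On the MM.1S panobinostat array alone, 56 miRNAs were detected that the main comparisons left out as seen on fewer than 2 arrays, 42 of them with names numbered from 1000, where the DMSO arrays had 2 (MM.1S) and 3 (KMS-11) such single detections.

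Changes were wider in MM.1S (SD 1.04 with panobinostat, 0.65 with vorinostat) than in KMS-11 (0.34 and 0.37). Brightness of the whole array is argued against. The spike-ins of the MM.1S panobinostat array moved by 3.06% of the shift in its 75th percentile. Compression by signal level stays open. With panobinostat, the SD left after a trend on mean signal was still 2.96 times that of KMS-11 (3.08 before the trend). With vorinostat the ratio was 1.75 both before and after it. The mean signal was taken over the arrays of both lines, whose levels differ for many miRNAs. A trend with the signal in MM.1S could therefore remain, and these ratios cannot decide the question. A shift between miRNAs numbered from 1000 and those numbered under 1000 cannot be the whole pattern: their medians differed by 0.78 with panobinostat but by 0.27 with vorinostat, under the KMS-11 SD of 0.355, and with panobinostat the SD was 1.1 in MM.1S against 0.27 in KMS-11 among those numbered from 1000, and 0.91 against 0.39 among those numbered under 1000. A stronger response of MM.1S at these doses may be an explanation, but with 1 array per line and drug a difference in the RNA of single cultures stays open as well. The interaction test called 0 of 362 miRNAs (limma, lowest adjusted p = 0.349, 45 at an unadjusted p under 0.05). It called 5 with normexp (miR-21-5p, miR-1260a, miR-3960, miR-4459 and miR-5100), and 22 and 26 with the value table as deposited and with 1 common floor. The counts of 10 with a floor 4 times higher and 1626 with no filter carry no weight, since many miRNAs sit at the floor there.

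miR-7-5p was lower on all 4 treated arrays. Scaling between arrays is argued against as the source of its sign, since with spike-in scaling the changes were −0.75 and −0.72 in MM.1S and −1.33 and −1.06 in KMS-11, with a spot error of at most 0.0653. One faulty probe is argued against too, since both of its probes were lower on every treated array, by −2.01 to −1.13. A change at the miR-7-1 precursor may be a candidate explanation: the opposite arm, miR-7-1-3p, was lower on all 4 arrays, the nearest to 0 being −0.61, and remained lower with spike-ins (−0.56, −0.43, −0.42 and −0.40), although its mean change was not called (adjusted p = 0.0843). A change in the other miR-7 precursors or in the turnover of miR-7-5p stays open and was not tested, as does the size of the change, which ran from −1.60 to −0.85 over the alternatives, with 9 of 24 calling it (limma adjusted p from 4.67e-07 to 0.942).

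The miR-17/miR-92a cluster had negative values in all 9 tested arms. A shift of MM.1S alone is argued against, since the KMS-11 median of −0.56 lay at percentile 0.01 of 10000 random lists matched on signal, the lowest percentile they can give (5th to 95th percentile −0.25 to 0.09), and the MM.1S median of −1.19 at percentile 0.03. Scaling is argued against as the source of the sign, since with spike-ins the list median was −0.34 with all 9 below 0, where the median of all tested miRNAs was 0.38 and the standard error of the list 0.05. The arms belong to 1 cluster and are not independent, and with an estimated correlation the list was not called (camera adjusted p = 0.878). Whether paralogous loci add to the signal of some arms was not tested. A lower level of the cluster's transcript under both inhibitors may account for the pattern, which remains a hypothesis since primary transcripts were not measured here.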

How the results depend on the processing

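Of the tests in this part, only the deposited value table with 1 common floor and the values in KMS-11 alone were chosen after the data were seen. KMS-11 alone gave 1 common miRNA and miR-7-5p at −1.40, with no test.

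Counts of calls went with how closely limma pooled the variances of the miRNAs. Over 19 settings that kept all arrays, the 7 with calls for both inhibitors had a prior of at least 50.2 degrees of freedom, and the 12 without any had at most 3.31. In the order panobinostat, vorinostat, both inhibitors, where the main counts were 8, 1 and 10, scaling by the median, quantile normalization, no scaling, spike-in scaling, the total gene signal of the scanner software, the brightest probe, the value table as deposited and with 1 common floor, a floor 4 times higher, a filter at 1 array or more, no filter and no replicate block each gave 0, 0 and 0 (limma, 0 to 49, 0 to 35 and 0 to 61 at an unadjusted p under 0.05). The 75th percentile over all miRNAs gave 3, 3 and 8, normexp background correction 16, 0 and 13 (20 for vorinostat at an unadjusted p under 0.05), a floor 4 times lower 17, 4 and 21, a filter at all 6 arrays 12, 1 and 16, an intensity trend 14, 1 and 14, and robust eBayes 4, 1 and 9. Only the DMSO and panobinostat arrays gave 0 (36 at an unadjusted p under 0.05), and only the DMSO and vorinostat arrays gave 25. Leaving out 1 array at a time gave 0 to 152, 0 to 39 and 0 to 153, and the lone array of a drug is then assumed to vary like the others.

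miR-7-5p kept its negative sign in every setting and lost its call for both inhibitors with median scaling (−1.42), quantile normalization (−1.40), no scaling (−1.02), spike-in scaling (−0.97), the brightest probe (−1.56), a floor 4 times higher (−1.31), and at −1.50 with the total gene signal, the value table in both forms, a filter at 1 array or more, no filter and no replicate block. Leaving out 1 array gave −1.60 to −1.40, and the call was also lost without the MM.1S DMSO, MM.1S vorinostat or KMS-11 vorinostat array. miR-129-2-3p reversed under normexp, to −0.20 with panobinostat and −0.13 with both inhibitors, where the cause was not tested. Under normexp the median of all tested miRNAs was lower still, at −0.39 with panobinostat and −0.29 with both inhibitors.

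KMS-11 against MM.1S gave 118 calls without scaling, 137 with normexp, 111 with the value table as deposited, 120 with 1 common floor, 56 with a filter at 1 array or more, 0 with no filter (126 at an unadjusted p under 0.05, limma), 0 with a floor 4 times higher (86), and 124 to 212 without 1 array, against 206. The interaction gave 5 calls with normexp, 22 with the value table as deposited, 26 with 1 common floor, 10 with a floor 4 times higher, 1626 with no filter and 0 to 90 without 1 array, against 0. With no filter or the higher floor, many miRNAs sit at the floor on most arrays, which lowers the estimated spread. Panobinostat against vorinostat gave 0 to 15 without 1 array, and 0 in every other setting (limma, 0 to 4 at an unadjusted p under 0.05).

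The common change of 1 miRNA became 0 with the 75th percentile over all miRNAs, no scaling, spike-ins, normexp and a fold minimum of 3, 2 with the total gene signal and the value table in both forms, 7 at a fold minimum of 1.5, and 1 to 2 without 1 array. The correlation between the lines of 0.50 became 0.37 with the 75th percentile over all miRNAs, 0.47 without scaling, 0.43 with spike-ins, 0.45 with normexp, 0.40 with the total gene signal, 0.20 with the value table as deposited, 0.18 with 1 common floor, 0.60 with a filter at all 6 arrays, and 0.38 to 0.56 without 1 array. Of lists, 2 were called, against 1 with quantile normalization, normexp, the value table in both forms, a floor 4 times lower, a filter at all 6 arrays and no replicate block, 5 with a filter at 1 array or more, 8 with no filter, 1 to 5 without 1 array, and 0 with an estimated correlation. The miR-17/miR-92a list was called as lower in each of 23 settings at the preset correlation (adjusted p from 2.1e-09 to 0.0439), and the paralog list in 13 of 23 (adjusted p from 0.00816 to 0.184). The causes of these shifts were not tested.

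Among named miRNAs, 38 called results gave 893 values under alternatives, of which 532 stayed called with their sign, 359 kept the sign without the call and 2 reversed. The 115 uncalled results gave 2721 values, with 2438 the same, 167 called and 116 of another sign but uncalled. Slide or scan as a block was not run, since there was 1 of each, and the interaction had no value without a DMSO array. Signal over background limits the dim miRNAs: 362 of 2006 miRNAs were tested.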

Other observations

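The miRNAs in this part were chosen after their values were seen, and the count over other splits of the arrays was planned.

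miR-21-5p, an oncogenic miRNA that is abundant in many tumours, had changes of −0.43 with panobinostat and −0.07 with vorinostat in MM.1S but 1.36 and 1.26 in KMS-11. On the mean of DMSO and both inhibitors it was 4.72 log2 units higher in KMS-11, a value that includes these changes. Its opposite arm, miR-21-3p, was undetected in MM.1S and changed by 1.26 and 1.11 in KMS-11. miR-34a-5p, a target of p53, had −0.82 and −0.52 in MM.1S and 0.65 and 0.59 in KMS-11, while miR-222-3p had −1.20 with either drug in MM.1S and 0.14 and 0.07 in KMS-11. The limma interaction values were 1.56, 1.29 and 1.31 for miR-21-5p, miR-34a-5p and miR-222-3p, each at an adjusted p of 0.349. miR-21-5p passed the interaction test with normexp (limma adjusted p = 0.0276). It also passed with no filter, but 1626 of 2006 miRNAs were called there, many of them at the floor, so that pass carries no weight. Without the MM.1S vorinostat array it passed as well, with 1 treated array left in that line. Over its other alternatives with all arrays the limma adjusted p was 0.0857 or higher. The negative values of miR-21-5p and miR-34a-5p in MM.1S are smaller than the shifts of 1.21 and 0.53 that scaling took out, so their sign rests on the scaling. The value of −1.20 for miR-222-3p with panobinostat is likewise smaller than 1.21, but that with vorinostat is larger than 0.53.

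miR-192-5p and miR-194-5p, which share precursor clusters and respond to p53, had positive values on all 4 treated arrays. Both were undetected on the MM.1S DMSO array, so their MM.1S values rest on the floor or on signal under detection there and are uncertain. miR-192-5p stood at 1.33 and 1.53 in MM.1S and 0.31 and 0.42 in KMS-11, and miR-194-5p at 0.49, 0.63, 0.33 and 0.55. miR-22-3p was also positive on all 4, at 0.27 and 0.50 in MM.1S and 0.76 and 1.12 in KMS-11, with a mean of 0.66 that was not called (limma adjusted p = 0.189). Values were farther from 0 in MM.1S for miR-142-5p, a blood cell miRNA (−1.58 and −0.89 against −0.25 and −0.19 in KMS-11), and for miR-4454, the brightest miRNA on the arrays (−1.75 and −0.80 against −0.09 and −0.14).

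Counting any size of change after scaling, 132 miRNAs were lower under both drugs in both lines, against 84.4 for independent lines, and 46 were higher against 31.1. Lower in MM.1S and higher in KMS-11 were 33, and the reverse held for 15. miRNAs are not independent of each other, so these counts carry no test here.

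For KMS-11 against MM.1S, the 6 arrays allow 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 206 calls, as many as 1 of the 10 splits, itself, and the highest of the others gave 0. On the KMS-11 DMSO array the negative control spots had a mean of 70.1 and an SD of 2205, where the other 5 arrays had means of −0.05 to 0.73.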
